A study of Drosophila melanogaster with 8 samples.

How the data were processed

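Total RNA was extracted with TRIzol from single white prepupae of Drosophila melanogaster, at 0 hours after puparium formation, and biotin-labelled cRNA was hybridised to 1-colour Affymetrix arrays, per the labels' protocols. The 8 arrays formed 4 groups of 2: wild type females, wild type males, double mutant females and double mutant males. Wild type was the strain w1118, and the mutants carried mutations in both bap170 and bap180, the latter now named polybromo. Groups were taken from the sample titles, and each array held the RNA of 1 animal.

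The deposited values were intensities on a linear scale, processed by RMA per the submitters' processing notes. RMA corrects background, normalizes between arrays and summarises the probes of each probe set. The software, its version and any further scaling are not given in the sources used here. Array medians lay between 27.8 and 29.2 in females and between 33.2 and 35.0 in males, so the deposited arrays do not share 1 distribution, and scaling can move differences between the sexes. Differences of dim probe sets are compressed towards 0, because background makes up most of their signal.

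The values of 18952 probe sets were taken to log2, and 183 control probe sets were left out, which left 18769 for testing. The platform annotation gave 1 gene symbol for 13647 of these, several for 402 and none for 4720, and probe sets with several symbols were not named. Symbols were updated by gene identifier against a table of the Release 6 assembly, which changed 0 symbols, and 103 probe sets with 1 symbol had no match there. Each of 11982 genes was represented by its probe set with the highest mean over the 8 arrays. No coordinates are printed, because no build is named in the sources used here.

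Differences were tested with limma (version 3.58.1, in R 4.3.3) by lmFit and eBayes on the 4 group means, without a variance trend, with 4 residual and 3.03 prior degrees of freedom. The genotype effect was the mean of both within-sex differences, double mutant minus wild type. The sex effect was the mean of both within-genotype differences, male minus female. Within-group contrasts and the genotype by sex interaction came from the same fit. Benjamini-Hochberg adjustment ran over all tested probe sets, with a threshold of 0.05. Errors written after log2 differences are standard errors (SE) from this fit, with n = 4 arrays per genotype or sex, or n = 2 within a sex. The number of arrays limits the precision.

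The fit, the 29 gene lists, the rule for naming genes and the alternative settings were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the 29 lists. The naming rule took Bap170 and polybromo, and the 10 largest rises and 10 largest falls among called genes with the same sign in both sexes and no overlap between the 4 mutant and the 4 wild type arrays. It added up to 4 members per list with the lowest p, the 5 genes with the lowest p per direction within each sex, the 5 largest differences per direction for sex, and msl-2, Sxl, Yp1, Yp2, Yp3 and the Y-linked genes as a check of the sex labels. The genes roX1 and roX2 belonged to that check and are not analysed here.

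The fit was tested on simulated data with 200 changed probe sets among 18769. For the genotype effect it recovered 12.9% of log2 changes of 0.5, 85.2% of changes of 1 and 99.5% of changes of 2, and 5.12% of its calls were false. The simulated noise was normal and independent between probe sets and arrays, with variances from the fit, so rates on the real arrays can differ. Alternatives covered scaling, filters on dim probe sets, the variance prior, 1 probe set per gene, the replicate number as a block, array weights, a 2-fold threshold, the model and the omission of each array. Crossed replicate numbers were added after seeing the data. RNA quality was checked as the 3' minus 5' difference of control transcripts with an exact permutation test.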

Results

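Gene expression was measured on 8 arrays of single white prepupae, 2 females and 2 males of each genotype. Bap170 and polybromo are subunits specific to PBAP, a form of the Brahma (SWI/SNF) chromatin remodelling complex, and the main comparison asks which transcripts differ at the onset of metamorphosis when both are mutated. Replicates correlated across probe sets at r = 0.977 to 0.99, and arrays of different groups at r = 0.912 to 0.979. The first principal component (60.6% of the variance) parted the sexes and the second (17.6%) the genotypes. Replicate 2 of the double mutant males scored 26.7 on the first component, against 53.4 to 59.6 for the other males. The 3' minus 5' difference of Act5C was 0.47 ± 0.13 (log2, SD, n = 4) in mutants and 0.50 ± 0.13 in wild type (two-sided exact permutation p = 0.714), and the other control transcripts gave p = 0.371 to 0.657, where 0.0286 is the smallest possible. Medians of the spike controls were 8.92 and 9.02 (log2) in the mutant males and 9.30 to 9.44 on the other arrays.

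Transcripts of both mutated genes were lower in the mutants. Bap170 averaged 5.88 ± 0.19 (log2, SD, n = 4) in mutants and 7.20 ± 0.22 in wild type, a difference of -1.32 ± 0.12 (SE, limma adjusted p = 0.00264). The difference of polybromo was -1.63 ± 0.12 (adjusted p = 0.00121), with -2.16 in females and -1.10 in males. Its mutant means of 4.04 in females and 4.19 in males lay below the medians of the mutant arrays (4.80 to 5.13). Wild type means were 6.20 in females and 5.29 in males. Signal this low compresses differences, so the falls may be understated and their sizes cannot be compared between the sexes. The stricter filter on dim probe sets removed polybromo. Of 8 measured Brahma complex subunits Bap170 and polybromo fell and no other was called, also adjusted over the list alone. The gene osa, whose product belongs to the other form, BAP (0.37 ± 0.19, adjusted p = 0.509), and the shared subunit gene mor (0.16 ± 0.14, adjusted p = 0.775) did not pass. The Brahma list had a median of 0.06 and a mean of -0.27, which differ in sign (camera adjusted p = 0.473). The mutated subunits as a pair stood below other genes (camera adjusted p = 0.00024, and adjusted p = 0.55 with an estimated correlation). Fry, which tests against no change and not against other genes, gave adjusted p = 0.00402. Where the probes lie relative to the mutations was not analysed here.

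The largest rises in double mutants were those of CG10799, by 5.36 ± 0.67 (log2, SE, n = 4, limma adjusted p = 0.00963), and of MtnC, a metallothionein gene, by 5.06 ± 0.45 (adjusted p = 0.00259). CG33093 rose 17.8-fold and GILT3, a lysosomal thiol reductase gene, rose 17.7-fold (4.15 ± 0.13, adjusted p = 5.25e-05). LysX, a lysozyme gene, fell by 6.29 ± 0.25 (adjusted p = 7.38e-05), from 11.10 to 5.18 in females and from 11.47 to 4.81 in males. CG42846 fell by 5.65 ± 0.15 (adjusted p = 4.44e-05) and the cuticle protein gene Cpr97Ea fell by 3.50 ± 0.36 (adjusted p = 0.00448). The genotype effect called 524 probe sets in limma, 248 higher and 276 lower in mutants, with 307 at least 2-fold apart. An unadjusted p under 0.05 was reached by 2495, where chance gives 938. Leaving out a female array lowered the count to 260 or 247 (wild type replicates 1 and 2) and to 290 or 259 (mutant replicates 1 and 2).

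Further rises were those of CG30286 (3.32 ± 0.14), CG15404 (2.73 ± 0.20) and mag, a lipase gene of the gut (2.72 ± 0.23). Further falls were those of CG13962 (-4.26 ± 0.45), Cyt-b5-r (-3.89 ± 0.47), CG15905 (-3.75 ± 0.17), CG11865 (-3.27 ± 0.11), Jhbp7 (-3.09 ± 0.14) and CG2065 (-3.01 ± 0.40). CG40486 fell by 3.07 ± 0.17 on its representative probe set, while its other, dim probe set differed by -0.00. Of 438 genes called on their representative probe set 430 had 1 sign in both sexes, and in 381 of these the mutant and wild type arrays did not overlap. Random splits of 4 against 4 arrays give 2.86% for genes not chosen by their call, and the call itself favours a shared sign and no overlap, so these counts describe the called genes and test nothing further. The call of CG2065 ended without either wild type female or without replicate 2 of the mutant females (highest adjusted p = 0.0614).

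**Figure D1:**
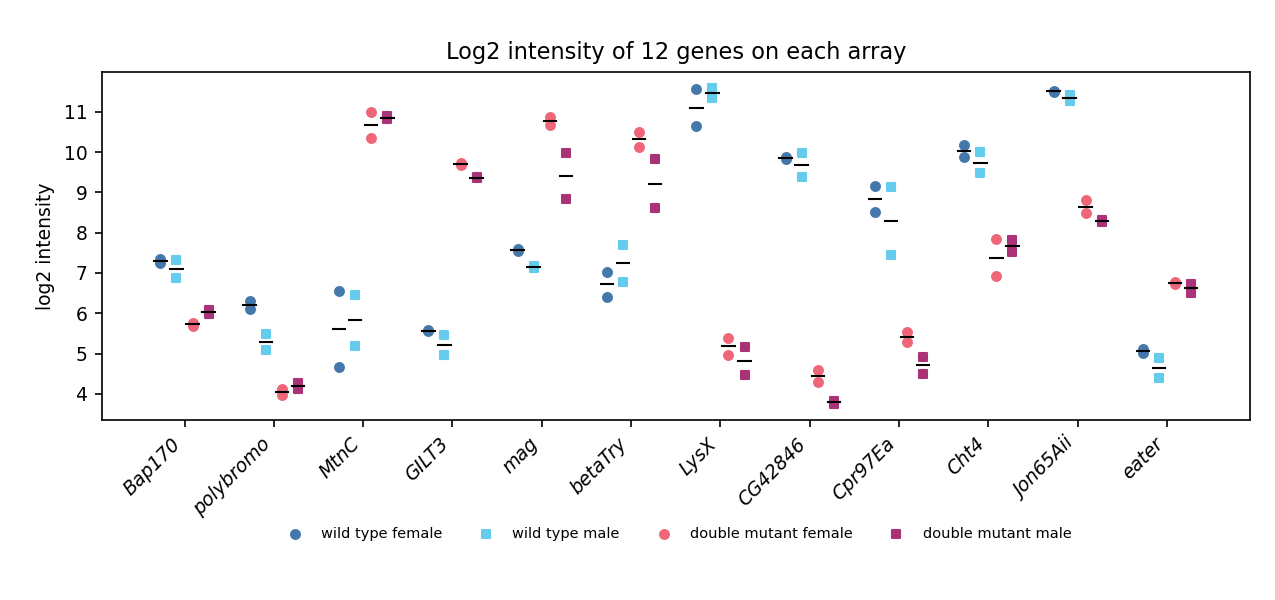
Log2 intensity of single genes (x axis) on each of the 8 arrays (y axis), with a point per array and a bar at the mean of the 2 arrays of a group. LysX lies between 10.64 and 11.60 in wild type and between 4.48 and 5.39 in mutants, and GILT3 between 4.96 and 5.58 in wild type and between 9.35 and 9.73 in mutants.

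Among 30 digestive enzyme genes of the midgut 6 rose in mutants and 1 fell, and adjusted over the list alone 9 rose and 1 fell. The serine protease genes Jon25Biii (2.91 ± 0.37, limma adjusted p = 0.0101) and betaTry (2.78 ± 0.33, adjusted p = 0.00776) rose, as did mag and the amylase-related gene Amyrel (1.66 ± 0.18, adjusted p = 0.00568). The protease genes etaTry (1.28 ± 0.19) and epsilonTry (2.15 ± 0.33), chosen after their values were seen, also rose, and without either mutant female both calls ended and the list held 4 rises. Jon65Aii, another protease gene of this list, fell by 2.96 ± 0.11 (adjusted p = 5.77e-05). The list median was 0.45 (camera adjusted p = 0.00024, and adjusted p = 0.572 with an estimated correlation). Fry, which tests a list against no change and not against other genes, gave adjusted p = 0.152. Per array the median stood at 0.29 and 0.58 in mutant females and at 0.05 and 0.65 in mutant males, relative to wild type of the same sex, and without mutant male replicate 2 the list median was 0.21.

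Among 21 genes of chitin synthesis and modification 4 fell and 2 rose, and adjusted over the list alone 4 fell and 3 rose. The chitinase genes Cht4 (-2.36 ± 0.23, limma adjusted p = 0.00345) and Cht10 (-1.49 ± 0.10, adjusted p = 0.000819) fell, together with the chitin deacetylase gene Cda4 (-1.40 ± 0.13) and Idgf5 (-0.95 ± 0.13). Idgf3 (1.57 ± 0.26, adjusted p = 0.0303) and Idgf4 (0.46 ± 0.09, adjusted p = 0.0479), which encode chitinase-like growth factors and were chosen after their values were seen, rose. Without either wild type female, either mutant female or wild type male replicate 2 the list held 0 rises, and without any other array 1. Another probe set of Idgf3 differed by 0.76 (adjusted p = 0.13), and the call of Idgf5 ended without wild type female replicate 1 (adjusted p = 0.053) or 2 (0.0674). The list median was -0.04 (camera adjusted p = 0.518), and in fry, which tests against no change, the list was lower (adjusted p = 0.0494). Of 28 larval and pupal cuticle genes Cpr66Cb fell by 0.99 ± 0.19 (adjusted p = 0.0468) and no other was called, with a list median of 0.01, a mean of -0.01 and a camera direction upwards, which differ in sign (adjusted p = 0.885). The call of Cpr66Cb ended without any 1 array other than wild type male replicate 1 (adjusted p up to 0.167), with the replicate number as a block and with crossed replicate numbers.

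The lists of the ecdysone response, the steroid cascade that starts metamorphosis, and of its late puff and glue genes held 1 or 2 calls each. Of 17 receptor and early regulator genes the nuclear receptor gene Hr96 rose by 0.72 ± 0.09 (limma adjusted p = 0.0112). Its place on the list does not make this rise a response to ecdysone. The genes usp (0.32 ± 0.09, adjusted p = 0.176) and Eip93F (-0.56 ± 0.20, adjusted p = 0.278) did not pass, and the list had camera adjusted p = 0.0533. Of 16 effector genes ImpE2 (-0.88 ± 0.14, adjusted p = 0.0242) and ImpL1 (-1.76 ± 0.34, adjusted p = 0.0473) fell (camera adjusted p = 0.337). Of 9 genes of the 71E late puff Eig71Eg fell by 1.67 ± 0.17 (adjusted p = 0.00445) and Eig71Ek rose by 2.93 ± 0.57 (adjusted p = 0.0491), and adjusted over the list alone 4 rose and 1 fell (camera adjusted p = 0.266). Without mutant female replicate 1 this list held 3 rises, and with 1 array left out its median of 0.37 lay between 0.10 (mutant female replicate 2) and 0.57 (wild type female replicate 2). Of 11 salivary glue genes Sgs5bis rose by 3.37 ± 0.66 (adjusted p = 0.0494) and Sgs1 fell by 0.65 ± 0.08 (adjusted p = 0.0103), and adjusted over the list alone 1 rose and 4 fell (camera adjusted p = 0.0956). Sgs4 differed by -4.37 ± 1.06 (adjusted p = 0.0997) and Sgs3 by -1.50 ± 0.31 (adjusted p = 0.0605). No gene was called, also adjusted over the list alone, among 13 genes of ecdysteroid synthesis (camera adjusted p = 0.289), 7 of the juvenile hormone pathway and 3 larval serum protein genes (camera adjusted p = 0.797 for both). The juvenile hormone list had a median of -0.02 and a mean of 0.03, which differ in sign.

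Single arrays decided several of these calls of the genotype effect. Sgs4 passed without mutant male replicate 1 (-5.76, limma adjusted p = 0.000204) or 2 (-2.99), Sgs3 without wild type male replicate 2 (-1.77, adjusted p = 0.0404), and both with a variance trend (adjusted p = 0.0308 and 0.0171). Without mutant male replicate 1 Eip93F passed (-0.80, adjusted p = 0.0294), and so did shd, a gene of ecdysteroid synthesis (1.80, adjusted p = 0.00336, against 1.29 and 0.207 with all arrays). The ecdysteroid list also held 1 rise without wild type male replicate 2. The glue list passed camera without replicate 2 of the wild type or the mutant males, the 71E list without mutant female replicate 1, and the early regulators without replicate 2 of the wild type females, mutant females or mutant males. The calls of Eig71Ek, Sgs5bis, ImpE2 and ImpL1 ended in 9, 10, 6 and 7 of 18 alternatives, with adjusted p up to 0.173 (without wild type female replicate 1), 0.174 (robust variance trend), 0.0952 (without wild type female replicate 1) and 0.171 (without wild type female replicate 2). Without wild type female replicate 2 the calls of Hr96 (adjusted p = 0.0574) and Sgs1 (0.0551) ended, and without mutant female replicate 2 that of Hr96 (0.054).

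The phagocytosis receptor gene eater rose by 1.83 ± 0.13 (limma adjusted p = 0.000894), the only called gene of 14 hemocyte markers, and adjusted over the list alone 5 rose and 1 fell. The GATA factor gene srp (0.75 ± 0.15, adjusted p = 0.0531) and the prophenoloxidase gene PPO2 (1.76 ± 0.42, adjusted p = 0.0954) did not pass. With a variance trend both passed, srp also in 5 other alternatives, and PPO2 also without wild type female replicate 1 (2.29, adjusted p = 0.00329) or 2 (1.22, adjusted p = 0.0258). The hemocyte median was 0.24 (camera adjusted p = 0.0362, and adjusted p = 0.55 with an estimated correlation), with adjusted p = 0.00402 in fry, which tests against no change. None of 18 antimicrobial and immune genes was called by limma, also adjusted over the list alone, with Rel at 0.55 ± 0.14 (adjusted p = 0.124) and Drs at 0.68 ± 0.21 (adjusted p = 0.194). The immune median was 0.55 (camera adjusted p = 0.00357, and adjusted p = 0.6 with an estimated correlation), at 0.08 and 0.46 in mutant females and at 1.05 and 0.18 in mutant males relative to wild type of the same sex. For the hemocyte markers the list call ended after repeated quantile normalization (adjusted p = 0.0934) and without wild type male replicate 2 (0.145) or mutant female replicate 2 (0.0524). Rises among the hemocyte markers numbered 3, 2 and 3 without wild type female replicate 1, wild type female replicate 2 and mutant male replicate 2, and without the last 3 immune genes rose. For the list antimicrobial and immune response, genotype effect tests no longer passed camera without mutant male replicate 1 (adjusted p = 0.0538, list median 0.17), and fry gave adjusted p = 0.155.

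**Figure D2:**
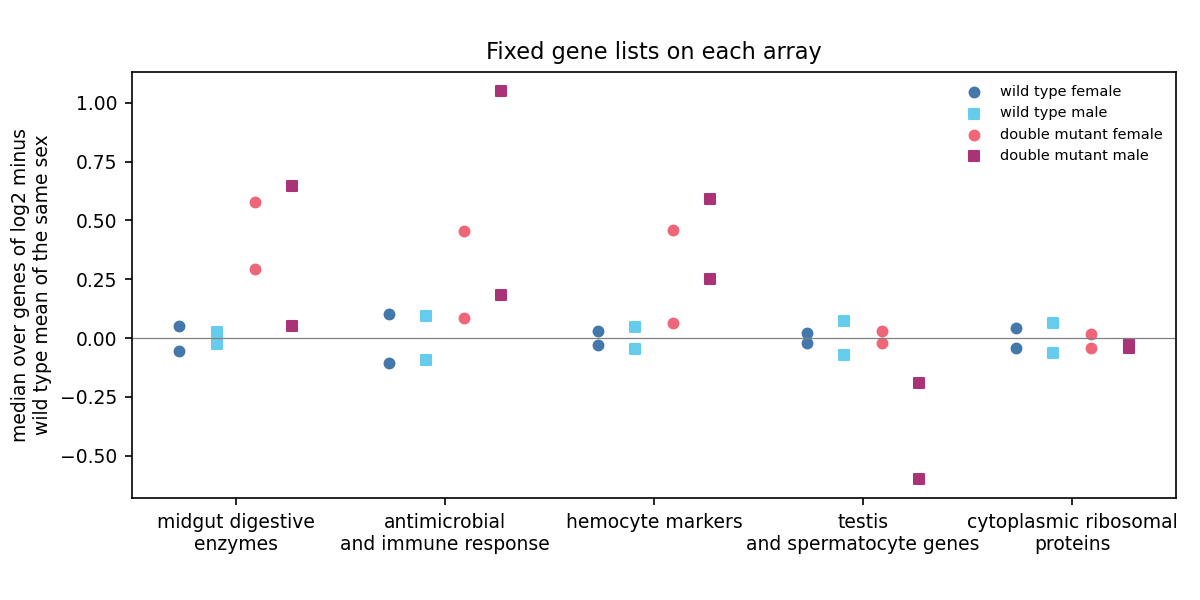
For fixed gene lists (x axis), the median over genes of log2 intensity minus the wild type mean of the same sex (y axis), with a point per array. The testis list stands at -0.19 and -0.60 in the mutant males, and the immune list at 1.05 in replicate 1 of the mutant males.

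Other lists held 1 or 2 calls. Atg1, the kinase gene that starts autophagy, rose by 0.92 ± 0.09 (limma adjusted p = 0.00421) and the Bcl-2 relative Debcl, among the 50 genes nearest to Bap170 on a side, fell by 0.86 ± 0.16 (adjusted p = 0.0396) among 23 genes of autophagy and cell death (camera adjusted p = 0.523). Of 13 heat shock and stress genes the glutathione transferase gene GstE1 fell by 2.27 ± 0.31 (adjusted p = 0.0141) and the co-chaperone gene stv rose by 0.89 ± 0.14 (adjusted p = 0.0239, camera adjusted p = 0.0971). The troponin C gene TpnC73F fell by 0.76 ± 0.13 (adjusted p = 0.0351) among 18 muscle genes (camera adjusted p = 0.518). The germline differentiation gene bam rose by 0.56 ± 0.09 (adjusted p = 0.025) among 20 female and germline genes (2 adjusted over the list alone, camera adjusted p = 0.473). Both filters on dim probe sets removed bam. The helicase gene mle rose by 0.95 ± 0.13 (adjusted p = 0.0139) among 14 genes of sex determination and dosage compensation (2 adjusted over the list alone, camera adjusted p = 0.2). Of 31 testis and spermatocyte genes vis, a homeodomain gene, rose by 2.16 ± 0.17 (adjusted p = 0.00121), while its near-identical neighbour achi, chosen after its values were seen, differed by -0.25 ± 0.10 (adjusted p = 0.337, list camera adjusted p = 0.0971). Without replicate 1 of the mutant males or females the testis list passed camera. The calls of Debcl, TpnC73F and bam each ended in 8 alternatives and that of stv in 5, with adjusted p up to 0.146, 0.131, 0.103 and 0.0952, all without a wild type female array. Without wild type female replicate 1 or 2 the calls of GstE1 (adjusted p = 0.0518 and 0.0667) and mle ended, and so did that of mle without mutant female replicate 2 (its highest adjusted p, 0.065).

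No member was called for the genotype effect, also adjusted over the list alone, in 9 further lists. These were 4 homeotic genes, 14 neuronal markers and 11 glycolysis genes (camera adjusted p = 0.473 each), and 8 genes of the Egfr pathway (0.848). They also held 21 genes of imaginal disc patterning, 9 fat body markers, 37 ribosomal protein genes and 7 Y-linked genes (camera adjusted p = 0.518 each), and 19 genes of the cell cycle (0.956). In at least 1 alternative setting the disc gene ac (-1.06 to -0.64 over the alternatives) and the fat body marker Lsd-1 (-1.61 to -0.76) passed. Some lists were measured in part, with 4 of 8 homeotic, 8 of 13 Egfr pathway and 19 of 28 cell cycle genes. Array medians were 3.49 to 3.77 (log2) for the Y-linked list and 4.74 to 5.37 for the neuronal markers. Signal this low can hide differences, so the missing calls there say little.

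In females CG6296 rose by 3.72 ± 0.14 (SE, n = 2, limma adjusted p = 0.000339), and in males by 1.18 ± 0.14 (adjusted p = 0.0175). The gene fusl rose by 2.41 in females and 2.70 in males, and CG10353 by 2.32 and 2.98. Digestive enzyme genes of the midgut stood higher in mutant females (camera adjusted p = 6.78e-06, and adjusted p = 0.626 with an estimated correlation), as did hemocyte markers (adjusted p = 0.0282, and 0.541 with an estimated correlation). The mutated subunits stood lower in females (adjusted p = 1.76e-05, and 0.495 with an estimated correlation). The list of Brahma complex subunits, which holds both of them, passed too (adjusted p = 0.0118, and 0.626 with an estimated correlation), while its other 6 members lay between -0.35 (Snr1) and 0.24 (osa) and none of these was called. In males the mutated subunits stood lower (adjusted p = 0.00402, and 0.76 with an estimated correlation) and immune genes higher (0.00825, and 0.76). In fry, against no change, the mutated subunits passed in females (adjusted p = 0.00694) and in males (0.028), and hemocyte markers in males (0.0263). The genotype effect in females called 177 probe sets, 60 higher and 117 lower, and the genotype effect in males 197, 92 higher and 105 lower. Of these, 108 were called in both sexes, all in the same direction. Independent lists would share 1.86. Both tests use 1 variance estimate per probe set from the same fit, so the lists are not independent and this figure tests nothing. Over all probe sets the female and male differences correlated at r = 0.561, across probe sets, which are not independent replicates. Among probe sets called for genotype, chosen on the mean of both differences, which favours a shared sign, r was 0.925 and 98.5% had the same sign. The genotype by sex interaction called 0 probe sets in limma, with 1184 at an unadjusted p under 0.05. The female count lay between 44 and 73 without 1 of the female arrays, and the male count was 105 without wild type male replicate 1, 122 without either wild type female and 126 without either mutant female. With only the 4 male arrays 23 were called in males, and without replicate 2 of the mutant males the interaction called 20.

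**Figure D3:**
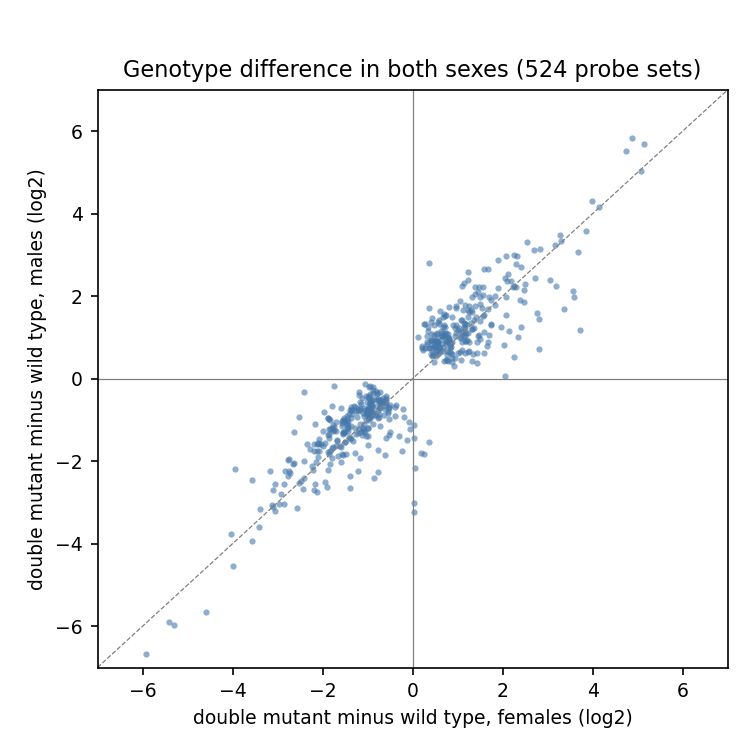
Genotype difference in females (x axis, log2) against that in males (y axis, log2), with a point for each of the 524 probe sets called for genotype and a line of equality. These were chosen on the mean of both differences, and over all probe sets r is 0.561.

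In mutant males the testis and spermatocyte list had a median of -0.43 over 31 genes (camera adjusted p = 0.00123, and adjusted p = 0.76 with an estimated correlation). The only called member, vis, rose by 2.65 (limma adjusted p = 0.00499). Mst84Dc (-0.88, adjusted p = 0.213) and Mst84Da (-0.95, adjusted p = 0.173), genes of sperm proteins, did not pass. The list medians were -0.19 in replicate 1 and -0.60 in replicate 2 of the mutant males, whose spike controls stood at 8.92 and 9.02.

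Genes of the testis led the differences between the sexes. CG9920 was higher in males by 7.23 ± 0.15 (log2, SE, n = 4, limma adjusted p = 3.62e-06), CG12699 by 7.17 ± 0.20, the thioredoxin gene TrxT by 6.75 ± 0.19, ocn by 6.65 ± 0.19 and CG15219 by 6.51 ± 0.25. Of 31 testis and spermatocyte genes 26 were higher in males, and 27 adjusted over the list alone (camera adjusted p = 2.89e-25, and adjusted p = 0.257 with an estimated correlation). The sex regulator dsx was higher in females on 1 probe set (-3.71 ± 0.10, male minus female) and lower on another (0.83). The yolk protein gene Yp3 differed by -3.73 ± 0.52 (adjusted p = 0.00315), with means of 6.06 in wild type and 10.34 in mutant females and of 4.48 and 4.46 in males. Also higher in females were hll (-2.39 ± 0.32), CG42834 (-2.19 ± 0.51) and CG11911 (-2.09 ± 0.46). The calls of CG42834 and CG11911 ended without wild type female replicate 2 (adjusted p = 0.134 and 0.0806) or mutant female replicate 2 (0.125 and 0.1), among other arrays.

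As a check of the sex labels, the dosage compensation gene msl-2 was higher in males by 0.91 ± 0.10 (limma adjusted p = 0.00114). The representative probe set of Sxl differed by -0.46 ± 0.21 (adjusted p = 0.221) and another by -1.16 (adjusted p = 0.00866). Yp1 (-0.17 ± 0.13) and Yp2 (-0.26 ± 0.14) did not pass, and after median centring Sxl, Yp1 and Yp2 did (adjusted p = 0.019, 0.0245 and 0.0206). Median centring lowers the male minus female difference of every probe set by the same amount, so these passes do not check the sex labels. Of 7 Y-linked genes ARY was higher in males by 0.44 ± 0.09 (adjusted p = 0.0223), a call that ended after median centring (adjusted p = 0.133) and without 7 of the single arrays. Of 30 midgut enzyme genes 8 were higher in females, and 11 adjusted over the list alone (camera adjusted p = 0.00133, and adjusted p = 0.816 with an estimated correlation). This count was 2 without mutant female replicate 2, 3 without wild type male replicate 1, 4 without wild type female or male replicate 2, and 5 without replicate 1 of the mutant females or males. Of 37 ribosomal protein genes 7 were higher in males, also adjusted over the list alone, among them RpL10Aa (3.16 ± 0.23), and the list median of -0.01 and mean of 0.38 differ in sign (camera adjusted p = 0.098). No other list passed camera for sex. In fry, against no change, testis (adjusted p = 0.000337) and Y-linked genes (0.0426) passed as higher in males, and as higher in females the lists of sex determination and dosage compensation (0.00404), ecdysteroid synthesis (0.0169), chitin (0.0222), juvenile hormone and hemocyte markers (0.0267 each). The median sex difference of all probe sets was -0.13, so a list that only follows this offset can pass fry as higher in females.

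The sex effect called 1894 probe sets in limma, 1518 higher in males and 376 higher in females, so 80.1% were male-biased. Repeated quantile normalization gave 3476 calls, 45.6% of them male-biased, and centring arrays on their medians gave 12522, with 11.5%. The median difference of all probe sets was -0.13, and -0.40 after centring, so directions of differences of this size depend on the scaling. The sex effect in wild type called 1483, with 88.0% male-biased, 61.6% after repeated quantile normalization and 24.4% after centring. The sex effect in double mutant called 1178, with 90.6%, 71.1% and 46.2%. In both genotypes 1017 were called, all in the same direction.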

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

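The tests of single arrays, of other probe sets of a gene, of other stock differences and of gut tissue, and the power check of the testis test, were chosen after the results were seen.

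At the preset correlation 5 fixed lists passed camera on the genotype by sex interaction, each with adjusted p = 0.933 with an estimated correlation. The interaction called 0 probe sets in limma, so a difference between the sexes is not established. Spike control medians were 8.92 and 9.02 in the mutant males and 9.30 to 9.44 on the other arrays. A processing difference of the mutant males cannot be told apart from the interaction. Spermatocyte genes had median differences of 0.02 in females and -0.43 in males (adjusted p = 5.5e-05). Brahma complex subunits stood at -0.27 and 0.30 (adjusted p = 0.0026), and the mutated subunits at -1.87 and -1.08 (adjusted p = 0.044). The Brahma list holds both mutated genes, and none of its other members was called for the interaction (lowest limma adjusted p = 0.766). Array medians of the mutated pair were 4.9 and 4.9 (log2) in mutant females and 5.1 and 5.1 in mutant males. In wild type they were 6.7 and 6.8 in females and 6.0 and 6.4 in males, so wild type males started lower. Cell cycle genes stood at -0.25 and 0.24 (adjusted p = 0.00425) and cuticle genes at 0.11 and -0.07 (adjusted p = 0.0392).

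Spermatocyte genes had lower medians in mutant males, and of 259 genes at least 3 log2 units higher in males 252 had lower means in mutant males, 2 of them called (limma adjusted p under 0.05), with a median of -0.64, and of 0.02 in females. A smaller share of testis RNA in mutant males may lower such genes alike, and after each array's median shift was taken out 0 percent of them still differed (limma on 4 arrays, 5.41% at an unadjusted p under 0.05). That test stays open, because it recovered only 16.4% of planted changes of 1 log2 unit. A single divergent animal stays open too, since the array medians were -0.28 and -1.01 in the mutant males and the higher lies closer to wild type than to the other mutant. An effect of the mutations on spermatocyte genes was not tested apart from these.

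Large single-gene differences, such as those of LysX, CG42846 and GILT3, may come from the stocks and not from the mutated subunits. Against variants linked to the mutated loci, 4 of 130 genes among the 50 nearest on each side of Bap170 and polybromo were called, Debcl among them, and 432 of 11850 other genes (odds ratio 0.84, 95% interval 0.22 to 2.22, Fisher's exact p = 1). More distant genes on the same chromosomes counted among the others, and the interval reaches 2.22. This test therefore bears only on a large excess close to the loci. Sequence variants under single probe sets stay open, because only 7 of 247 genes called at least 2-fold have another bright probe set, whose change was a median 1.06 of the called one and 0.448 of it in Orai. Other stock differences between w1118 and the mutant line cannot be told apart from the mutations, as 0 arrays held a further genotype. An effect of the mutations stays open.

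Digestive enzyme genes stood higher than other genes as a list at the preset correlation (camera adjusted p = 0.00024), and adjusted p = 0.572 with an estimated correlation, so the list difference itself is not established, and animals of different age within the stage could give it. More gut tissue would raise abundant members alike, and of 15 such members 7 had a 95% interval wholly below a rise of 1 log2 unit and 4 wholly above it, which argues against it as the whole cause. For age, the genotype difference of the 30 genes was correlated with the axis along which animals of 1 group differ. Across genes, which are not independent, r was -0.21 (permutation p = 0.261, 95% interval -0.54 to 0.15). The stress and immune genes TotB, BomT2 and BomS2 have some of the highest weights on this axis, and whether it follows age was not tested. The correlation therefore decides nothing about age. An effect of the mutations stays open.

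The 18 splits of the arrays balanced over the other factor are too few for a share under 0.05. The real genotype split called 524 probe sets and the highest other 0, and the real sex split called 1894 and the highest other 3, so 1 split of each reached the real value.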

How the results depend on the processing

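The crossed replicate numbers were chosen after seeing the data. Among 2932 comparisons of named genes with alternatives 2775 kept their side of the threshold, 108 lost the call, 49 gained one and 0 reversed. Most named genes were not called with all arrays and had no call to lose. The 108 losses therefore fall on the called genes alone, and the 2775 do not measure how stable calls are. The genotype effect (524) became 307 at a 2-fold threshold and 247 to 488 with 1 array left out, lowest without the female arrays. The genotype effect in females (177) became 278 with a robust variance trend and 44 to 173 with 1 array left out (73 and 44 without wild type female replicates 1 and 2, 58 and 48 without mutant female replicates 1 and 2). The genotype effect in males (197) became 23 with only the 4 arrays compared and 105 to 272 with 1 left out. The genotype by sex interaction (0) became 5 with a variance trend, 9 with a robust one and 0 to 20 with 1 array left out, 20 without mutant male replicate 2 and 1 without replicate 1 of the wild type females, wild type males or mutant females. The sex effect (1894) became 3476 after repeated quantile normalization, 12522 after centring, 1133 without the dimmest 50% of probe sets, 1251 at a 2-fold threshold and 1418 to 1843 with 1 array left out. The sex effect in wild type (1483) became 5240 after centring, 953 without the dimmest probe sets and 943 to 1454 with 1 array left out (943 without wild type female replicate 2). The sex effect in double mutant (1178) became 2124 after centring and 681 to 1308 with 1 array left out (730 and 681 without mutant female replicates 1 and 2, 781 without mutant male replicate 1). The gene list tests (4 lists) became 0 with an estimated correlation and 4 to 6 with 1 array left out. Fewer probe sets or arrays entered the filtered and left-out settings, and for the others the cause was not tested. A group left with 1 array is assumed to vary like the others. Replicates share only a number: their differences correlated at 0.184 to 0.413 among 3 groups and at -0.304 to -0.178 with the mutant males. With the replicate number as a block the counts were 447 for the genotype effect, 133 in females, 183 in males, 0 for the interaction, 1846 for the sex effect, 1453 in wild type, 1132 in mutants and 5 lists. Crossing the numbers of the mutant males gave 802, 288, 312, 0, 2332, 1771 and 1324 in the same order without lists. Signal close to background limits what dim probe sets can show.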

Other observations

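The genes described here were chosen after their values were seen. Some immune effector genes and the stress gene TotB were high in single mutant animals. BomS2, a peptide gene of the Toll response, stood at 11.58 (log2) in replicate 2 of the mutant females and at 9.61 in replicate 1 of the mutant males, and between 3.18 and 3.78 on the other 6 arrays. BomT2 stood at 11.53 and 10.26 in the same animals, and CG6788 at 11.13 and 12.05. The stress gene TotB reached 13.54 in that male, and lectin-24A 12.76 there and at most 4.10 on any other array. None was called for genotype (BomS2 3.76 ± 1.88, SE, n = 4, limma adjusted p = 0.486). These genes are among the 8 with the highest weights, with CG43085, CG42792 and CG33462, on an axis with 48.2% of the variance within groups.

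Both bright probe sets of the transferrin gene Tsf1 were higher in mutants (1.83 and 2.13), as were those of Vajk2 (2.26 and 2.28) and Karl (1.20 and 1.18), and both were lower for Arc1 (-1.62 and -2.36), all with limma adjusted p under 0.05, and Gnpnat and CG14823 also kept their direction past it. Orai had 1.22 on its called probe set and 0.55 on the other (adjusted p = 0.412). The share of genes called for genotype was 2.46% on the X chromosome, 3.40% on 2L, 4.20% on 2R, 4.69% on 3L and 3.33% on 3R, and 6.15% on chromosome 4, where 4 of 65 genes were called, all lower in mutants. No test of these shares was made. Of 80 gene families formed by symbol, none passed Fisher's exact test after adjustment, while camera passed Vps (adjusted p = 0.0137), RhoGAP (0.0375) and Tim (0.044), each with adjusted p = 0.914 with an estimated correlation.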
